A study of Mus musculus with 6 samples.

How the data were processed

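The study profiled RNA from mouse late spermatocytes, the germ cells near the end of meiotic prophase, in 6 libraries. Per the labels, 3 libraries came from Miwi+/- animals and 3 from Miwi-/- animals on a mixed genetic background. Miwi is the protein name of the gene Piwil1, a PIWI-family protein that binds pachytene piRNAs. Per the labels' protocols, RNA was extracted with Trizol and sequenced with standard Illumina library preparation, and the libraries are described as directional, that is, strand-specific. The submitters' processing notes name TopHat, Bowtie and the mm9 build. Their roles, their versions and the gene annotation are not given in the sources used here.

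The deposited table holds 10488 lines of 8 fields and starts directly with a gene, without a line of column names. Field 1 is an Ensembl gene ID and field 2 a gene symbol. The other 6 fields hold decimal values whose unit is not given in the sources used here. No name ties any of these 6 columns to a library or a genotype. Neither the order of the columns nor the level of a gene such as Piwil1 was taken as a label, so these 6 columns were left out of every step. No expression level, sequencing depth, fold change or test between genotypes is therefore given. The planned limma model, gene set tests and rule for naming genes, fixed before the data were examined, had no named columns to run on.

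What was analysed is which genes the table lists. The rule by which the authors chose the listed genes is not given in the sources used here, so listing is not read as a level of expression, and a gene that was not found may have been left out for reasons other than its level. The table gives a single set of genes with no library or genotype named, so listing cannot be tied to either genotype.

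Genes were matched to the GENCODE M21 annotation (assembly GRCm38) by Ensembl ID without the version, or by symbol. Of the 10488 IDs, 10324 (98.4%) were in that annotation and 164 were not. Among the matched IDs, 1304 had another symbol in the annotation than in the table. Of 21951 annotated protein-coding genes, 10151 were found by ID and another 96 by symbol only, so 10247 (46.7%) counted as listed. The annotation served only for names, gene types and chromosomes. No coordinates were used, because the notes name another build.

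The share of protein-coding genes listed was computed per chromosome. The X and the Y were each compared with the 19 autosomes together by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over these 2 tests. The 19 gene lists (germ cell stages, other testis cells, piRNA pathway, stress responses, housekeeping groups) were written before the data were examined. The use made of them here, a test of whether their members are listed more or less often than the other protein-coding genes, was chosen afterwards. Each list was tested by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 19 lists. Of the 486 list entries, 4 symbols (Ngn3, Hbb-b1, Hbb-b2 and Rbmy1a1) had no unique match in the reference and were left out, and synonyms of one gene were counted once. Genes are not independent replicates, so these p-values describe the gene sets and not a spread between animals. The members of lists that are named were chosen after it was seen which were listed. Pools of 7 germ cell lists (meiotic prophase, meiotic division, spermatid, spermiogenesis regulators, testis energy metabolism, axoneme and tail, piRNA pathway) and of 4 lists of other testis cells were also formed afterwards. On simulated gene sets of 900 genes against 20000, the test called 3.5% of 200 draws with no difference, and 100% of draws at an odds ratio of 0.5, which bears on the X chromosome alone. For sets of 12 genes, the size of the smallest list tested, unadjusted p-values called 3.5% of draws with no difference, 55% at an odds ratio of 0.25 and 88% at an odds ratio of 9. For sets of 20 genes these shares were 4.5%, 79% and 99.5%. The simulated genes were drawn independently of one another. These rates therefore do not cover related or neighbouring genes that are listed or left out together, nor the spread between whole chromosomes. The 5 alternatives tried were matching by ID only, matching by symbol only, limiting the annotation to Ensembl numbers up to the highest in the table, the RefSeq GRCm38.p6 protein-coding genes joined by symbol, and the germ cell pool with the spermatogonia and testis histone lists added. Computations used Python 3.11.15, pandas 2.3.3 and scipy 1.17.1.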

Results

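The series was designed to ask how the late spermatocyte transcriptome differs between Miwi-/- and Miwi+/- mice, with 3 libraries of each genotype. Late spermatocytes are the cells in which pachytene piRNAs, the small RNAs bound by MIWI, accumulate. The value columns of the table carry no library names, and no comparison of the genotypes was made. The data described here are the genes that the table lists for these cells, whatever their level or genotype.

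The table listed 10488 genes, each with its own Ensembl ID. Protein-coding genes made up 10151 of the IDs found in the annotation. Another 97 were pseudogenes, of which 77 were processed pseudogenes (11 of them annotated as transcribed), the reverse-transcribed copies of mRNAs that can share reads with their parent genes. The long non-coding classes were small, with 32 lincRNA genes and 23 antisense genes. Piwil1 itself was listed, as were Stambp and Golga2, which were chosen beforehand as reported targets of pachytene piRNAs.

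Genes of meiosis were listed nearly completely. All 30 genes of the meiotic prophase list were present, including Sycp1 and Sycp3 of the synaptonemal complex, the recombinase gene Dmc1 and Spo11, whose product makes meiotic DNA breaks. Of the 25 genes of the meiotic division list, 24 were present, among them Ccna1, Cdk1 and the chaperone gene Hspa2. Ccnb3 was the member not found. Both lists were present more often than the other protein-coding genes, of which 46.6% were listed (Fisher's exact test, adjusted p = 7.35e-10 for prophase and 1.15e-06 for division). Those other genes include large families with few listed members, such as Olfr olfactory receptors (3 of 1135 listed). They also include genes numbered above the table's highest Ensembl number. Both lower the share with which every list was compared.

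The genes of the piRNA pathway and of later sperm development were also mostly present. In the piRNA pathway list, 25 of 28 genes were listed, including Piwil2, Ddx4, Mael, Mov10l1, Tdrd1 and the transcription factor gene Mybl1. Piwil4, Tdrd5 and Btbd18 were not found (adjusted p = 9.43e-06 by Fisher's exact test for the list). In the spermatid list, 31 of 35 genes were listed. They included the transition protein genes Tnp1 and Tnp2, the protamine gene Prm2 and the acrosomal gene Acrv1. Prm1, Spem1, Tssk6 and Fscn3 were not found (adjusted p = 1.23e-06). The list of spermiogenesis regulators had 18 of 19 genes, including Crem and Rfx2, and lacked Camk4 (adjusted p = 3.82e-05). The list of axoneme and tail genes had 29 of 30, without Rsph4a (adjusted p = 1.95e-08). The testis energy metabolism list, with the glycolytic gene Pgk2 and the lactate dehydrogenase gene Ldhc, had 19 of 20 (adjusted p = 2.17e-05). The member not found, Ldhal6b, has an Ensembl number above the highest in the table. The testis histone list had 11 of 13 genes, including Hist1h1t, and lacked H1foo and Hist1h4a (adjusted p = 0.0148). Its listed members also include histone genes used by most cells, such as H3f3a, H3f3b and H2afz, so the result is not one of testis histones alone. Against RefSeq genes 3 members of that list could be matched, and all 3 were listed, too few to pass the test (adjusted p = 0.146).

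Groups used by most cells were near complete as well. All 30 genes of the deadenylation and mRNA decay list were present, including Cnot7 and the decay factor gene Upf1 (Fisher's exact test, adjusted p = 7.35e-10). Of 77 ribosomal protein genes, 75 were present, with Rpl10 and Rpl41 not found (adjusted p = 2.16e-21). The annotated ID of Rpl41 is numbered above the highest in the table.

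Markers of other testis cells were listed less completely than those of the meiotic and later germ cells. The 7 lists of meiosis, piRNA pathway and sperm development together had 176 of 187 genes listed (94.1%). With the spermatogonia and testis histone lists added, the count was 194 of 223 (87.0%). The 4 lists of Sertoli, Leydig, peritubular and endothelial, and immune and blood cells had 27 of 72 (37.5%). These pools were formed after the shares of the single lists had been seen and restate them. Among these 4, only the immune and blood list was below the other protein-coding genes by its own test, with 2 of 19 genes listed, H2-Ab1 and Hba-a1 (adjusted p = 0.00347). The peritubular and endothelial list had 5 of 19, namely Col1a1, Col1a2, Col3a1, Dcn and Sparc (adjusted p = 0.143). The Sertoli and Leydig lists stood above the other protein-coding genes (46.7%), at 63.6% and 50%, though neither passed its Fisher's exact test. The Sertoli list had 14 of 22, including Clu, Wt1, Cldn11 and Inha but not Sox9 or Amh (adjusted p = 0.171). The Leydig list had 6 of 12, including the steroidogenic genes Star, Cyp11a1, Cyp17a1, Hsd3b1 and Hsd3b6 (adjusted p = 1). Its members not found included Insl3, Lhcgr, Hsd17b3 and Nr5a1. The spermatogonia list had 8 of 24, including Gfra1, Id4 and Stra8 but not Kit or Zbtb16 (adjusted p = 0.264).

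Among the stress lists, the interferon response had 5 of 22 genes listed, which was below the other protein-coding genes at 46.7% (Fisher's exact test, adjusted p = 0.045). With genes matched by symbol only, the list still had 5 of 22 genes listed, the odds ratio was 0.424 in place of 0.336, and the difference no longer passed the test (adjusted p = 0.118). The p53 and DNA damage list had 11 of 20, including Bax and Mdm2 but not Cdkn1a (adjusted p = 0.534). The list of genes induced by tissue dissociation had 7 of 21, including Fos, Jun and Egr1 but not Fosb, Junb, Atf3 or Hspa1a (adjusted p = 0.308).

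**Figure D1:**
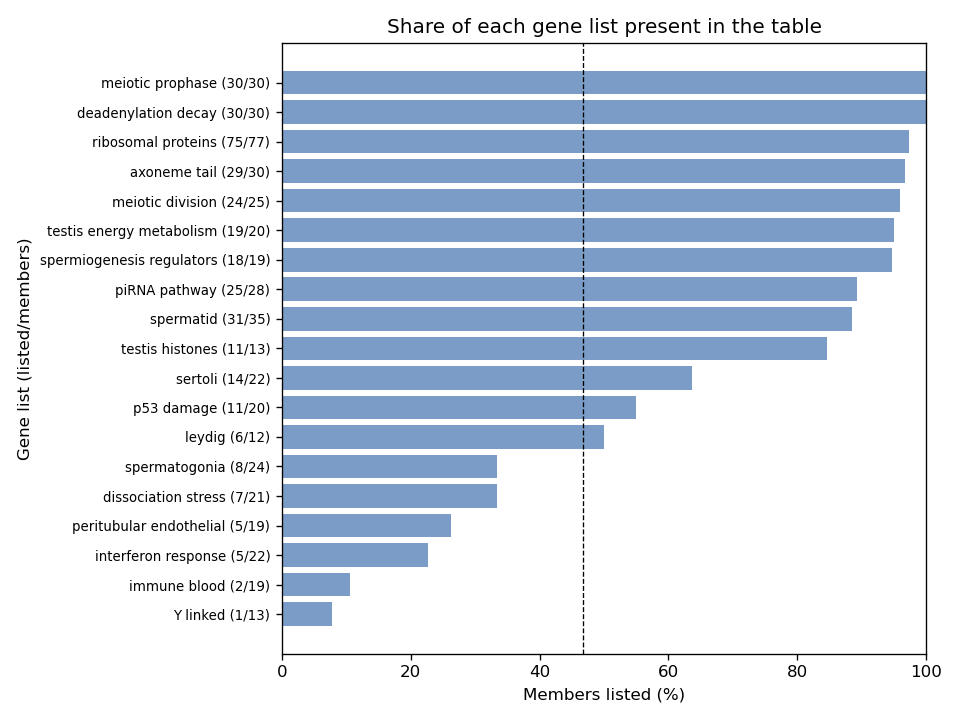
Share of each gene list that the table lists, in percent of its members, with the number listed and the number of members in parentheses. The dashed line is the share among all annotated protein-coding genes (46.7%), and the bars run from 30 of 30 meiotic prophase genes to 1 of 13 Y-linked genes.

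The X chromosome was listed far less completely than the autosomes. Of 948 annotated X-linked protein-coding genes, 203 were listed (21.4%), against 10043 of 20807 autosomal genes (48.3%). The 19 autosomes had a mean of 48.7% ± 4.91 (SD, n = 19) and ranged from 39.7% on chromosome 7 to 56.3% on chromosome 8, so the X lay below each of them. Fisher's exact test gave an odds ratio of 0.292 for the X (adjusted p = 1.12e-62, over genes). It counts each gene as independent and does not weigh the spread among the autosomes. X-linked genes that were listed included Akap4, Taf7l and Tex11.

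On the Y chromosome, 1 protein-coding gene was listed, Eif2s3y. The annotation holds 183 Y-linked protein-coding genes, but 12 of them have Ensembl numbers up to the highest in the table and the rest were numbered later. The share of 1 in 12 was below that of autosomal genes limited in the same way, 51.6% of which were listed (Fisher's exact test, p = 0.00263). Of the 13 genes in the fixed Y-linked list, the other 12, among them Zfy1, Zfy2, Uty and Ddx3y, were not found (adjusted p = 0.00737 for the list). Limited to the same Ensembl numbers, the list had 1 of 9 genes (adjusted p = 0.0323). None of the 13 protein-coding mitochondrial genes was listed.

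**Figure D2:**
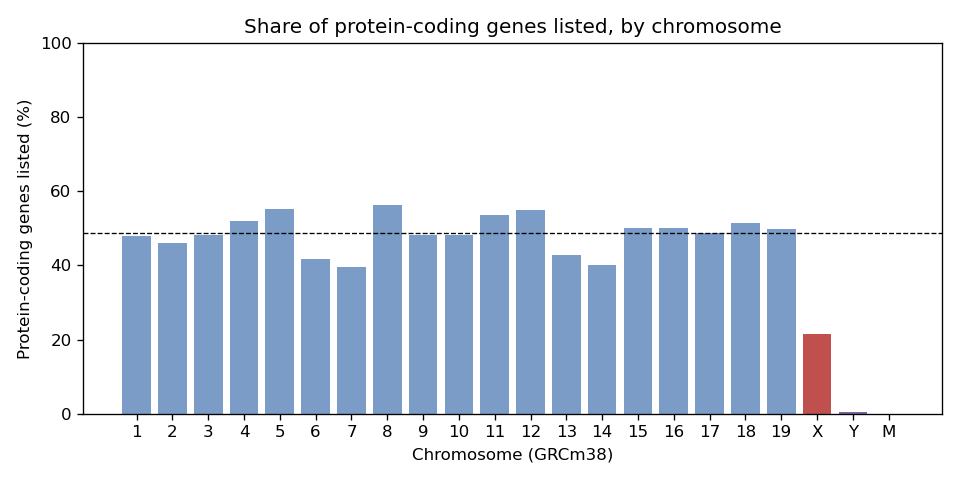
Share of annotated protein-coding genes listed in the table, in percent, for each mouse chromosome of the GRCm38 assembly, with M for the mitochondrial genome. The dashed line is the mean of the 19 autosomes (48.7%), and the X bar stands at 21.4%, below the lowest autosome at 39.7%.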

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

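All alternatives given here were chosen after the data were seen. Under 4 alternatives, matching by Ensembl ID only, matching by symbol only, limiting the annotation to Ensembl numbers up to the table's highest, and RefSeq genes, the X-linked share ranged from 19.4% to 24.2% and the autosomal share from 42.3% to 51.6%, and the X stayed below the autosomes by Fisher's exact test in each. The share of the meiotic, piRNA and sperm development lists ranged from 88.2% to 94.6%, and that of the other testis cell lists from 37.5% to 38.0%. Adding the spermatogonia and testis histone lists to the former gave 87.0%. Of 76 list tests under these alternatives, 74 kept their side of the threshold. The exceptions were the interferon list with symbols only (5 of 22 listed as before, adjusted p = 0.118) and the testis histone list with RefSeq genes, where 3 members remained, all listed (adjusted p = 0.146). No paired analysis was possible because the value columns carry no library names. For the same reason none of the alternatives planned before the data were examined was run: the replicate block, leaving out each library, the filters, normalizations, pseudocounts and library weights, and the set test with an estimated correlation. Depth per library is unknown here, so no limit of detection can be given for a gene that was not found.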

Other observations

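Protein-coding genes in none of the fixed lists also differed widely in how completely they were listed. They were grouped by the letters that start their symbol, and 110 groups had at least 20 named members. In 11 groups over 90% of the members were listed, and in 10 groups none was. All 49 Mrpl genes of the mitochondrial ribosome, all 28 Polr genes of the RNA polymerases and all 21 Nup genes of the nuclear pore were listed. So were 27 of 30 Cfap genes of cilia and flagella and all 33 Ddx helicase genes outside the fixed lists. Ddx3y, in the fixed Y-linked list, was not found. At the other end, 3 of 1135 Olfr olfactory receptor genes and 2 of 331 Vmn vomeronasal receptor genes were listed. None of 57 Krtap keratin-associated protein genes, 38 Tas taste receptor genes, 34 Scgb secretoglobin genes or 22 Mmp matrix metalloproteinase genes was found. These groups were formed after the data were seen and were not tested.

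The low share of X-linked genes was weighed against 2 technical explanations, with the tests written before their results but after the share itself had been seen. If the annotation held X-linked genes numbered too late to be in the table, limiting it to Ensembl numbers up to the table's highest would bring the X up to the lowest autosome. The X share was then 24.2% (202 of 835 genes), while the lowest autosome, chromosome 6, stood at 44.2% (Fisher's exact test against all autosomes, p = 1.23e-56). All autosomes together stood at 51.6%. If multicopy families and genes with placeholder names were the cause, leaving out such names and every symbol root of at least 5 genes would do the same. The X share was then 24.0% (75 of 313 genes), while the lowest autosome, chromosome 14, stood at 50.9% (Fisher's exact test, p = 3.3e-32). The autosomes together were at 57.5%. Without either limit the X stood at 21.4% and the autosomes at 48.3%, so neither limit narrowed the gap in percentage points. These values argue against either explanation as the main cause of the difference. The authors' rule for listing genes stays open, and no biological explanation was tested.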
